A study of Rattus norvegicus with 37 samples.

How the data were processed

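Total RNA from 37 rat tissue samples was hybridised to an Affymetrix whole-transcript rat gene array, 1 array per sample. Per the labels' protocols, implantation sites and uteri came from single animals, day 14 placentas were pooled within an animal, gestational day 1 was the day sperm were found, and RNA was extracted with TRIzol and a column kit. The labels name each animal, so the replicates are separate animals.

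The values used were the log2 expression values that the authors deposited as 1 table of all arrays. The submitters' processing notes name limma without a version, and the background correction, summarization and normalization behind the log2 values are not given in the sources used here. Array medians lay between 5.54 and 5.73 in the 27 uterine arrays and between 5.88 and 5.91 in the 10 placenta arrays, so levels were not compared between the uterine and the placental arrays. Of 36685 rows, 190 control rows were left out and 36495 probe sets were tested. The platform annotation gave 1 symbol for 18511 probe sets, several for 575 and none for 17409. Gene identifiers of 18394 of the named probe sets were found in the reference gene table (assembly GRCr8), and 0 symbols needed updating. Gene lists and gene names used 1 probe set for each of 18166 genes, the one with the highest mean; 291 genes had more than 1. No genome build was named, so no coordinates are given. No 2 arrays held identical values. On arrays, precision is limited by the number of arrays.

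Differences between groups were computed with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The 27 uterine arrays were fitted in 1 model of 6 groups, and the 10 placenta arrays alone. Contrasts were Dahl S minus Sprague Dawley at each of the 4 stages, day 7 minus virgin and day 10 minus day 7 within each strain, and the difference between the strains in each of those steps. All differences are on the log2 scale with limma's moderated standard error (SE). A total of 24 gene lists, covering cell types, placental zones, muscle, fat, inflammation, vascular, hypoxia, matrix, hormone and cell cycle genes, was tested with camera, also in limma, at its preset correlation of 0.01 with adjustment over the lists of a comparison, and again with an estimated correlation. None of the 71 list calls held with the estimated correlation, whose adjusted p is given beside the calls.

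These choices were made before the data were examined, as was the rule for named genes. That rule takes genes with a single, non-provisional symbol. For each strain comparison it takes the 10 largest rises and falls that passed, or all of them if fewer. It adds the 3 members with the smallest p of each called list, and 10 genes of the preeclampsia literature (Tnf, Vegfa, Pgf, Flt1, Eng, Hif1a, Agt, Agtr1a, Edn1, Nos3) where they passed or were needed. For gestation it takes the 6 largest changes each way, and for differences between strains in gestation the 6 largest each way or, where none passed, the 5 smallest p. Genes called in the same direction at several stages were also named. Genes named outside the rule are said to have been chosen after their values were seen.

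The scripts were tested on simulated values built from the real means and spreads, with 200 of 36495 probe sets changed. Noise was drawn independently for each probe set and array, so correlation between genes, which the real arrays hold, was not simulated. The recovery rates and the list check below apply to that setting only. At a 2-fold change, 77.6% of the changed probe sets were recovered in virgin uterus, 67.7% at day 7, 64.7% at day 10, 91.4% in placenta, and 51.7% and 43.4% for the strain differences in the day 7 and day 10 steps. At 1.5-fold, recovery was 33.3%, 31.0%, 38.0% and 71.9% at the 4 stages. Of 24 simulated lists, the 1 moved list was called, and so was 1 of the unmoved lists.

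Batches were looked for in the array's own control probes. The mean of 7 background control probe sets separated the uterine arrays into 15 with levels up to 1.96 and 12 with levels from 2.10 up, and the groups took unequal shares of these background sets. Low and high arrays numbered 5 and 0 in Dahl S virgin uterus, 3 and 2 in Sprague Dawley virgin uterus, 1 and 3 in Dahl S day 7, 0 and 5 in Sprague Dawley day 7, and 3 and 1 in each day 10 group. Placental arrays had no such gap but were ordered by strain, with the 5 Dahl S pools at 2.11 to 2.15, Sprague Dawley pool 46 among them at 2.11, and the other 4 Sprague Dawley pools at 2.18 to 2.21. The running numbers that open the titles of the uterine samples repeat between groups and form 2 consecutive series, from 1 to 12 and from 1 to 15, whose meaning the labels do not state. The shorter series holds 3 arrays of each virgin and each day 10 group, and the longer holds the other virgin and day 10 arrays and all day 7 arrays. Every high-background array carries a number from 4 up in the longer series. Numbers 1, 2, 8 and 9 fall to 2 arrays of 1 group each, and these were assigned by their background; all 16 possible assignments were also fitted. Uterine results are therefore also given with the background set or the number series as a block, and within each set or series that holds both groups, which are choices made after seeing the data. The strain differences themselves do not change with the series block, because both strains hold equal shares of the series at each stage. Placental results are also given with this division of 6 and 4 pools as a block, where the strain difference rests on pool 46 against the Dahl S pools, and with the background level as a covariate, both chosen after seeing the data.

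Alternatives tried were all 37 arrays in 1 fit, only the groups compared, only probe sets above the median level, quantile normalization, no trend, a robust trend, array weights, 1 probe set per gene, and leaving out each animal in turn. Fits without Sprague Dawley animals 60 and 43, which lay far from their groups, were added after seeing the data.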

Results

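The arrays followed the reproductive tract of 2 rat strains from before pregnancy to day 14 of gestation. Dahl S rats, an inbred salt-sensitive line that is hypertensive and serves as a model of preeclampsia superimposed on chronic hypertension, were compared with Sprague Dawley rats, an outbred stock with normal blood pressure. Virgin uterus was sampled from 5 Dahl S and 5 Sprague Dawley rats, day 7 implantation sites from 4 and 5, day 10 implantation sites from 4 and 4, and pooled day 14 placenta from 5 and 5. The design asks when in gestation the strains diverge and in which genes.

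Stage of gestation ordered the uterine arrays more than strain did. The first principal component of the 27 uterine arrays carried 22.9% of the variance and ran from virgin uterus to day 10 sites. The second component, which carried 12.0%, was highest in day 7 sites but also followed the 2 series of running numbers in the titles, of which the longer holds all day 7 arrays. Virgin arrays of the longer series, as assigned by background, lay between -6.38 and 10.2 on it, and those of the shorter series between -35.7 and -16.3. Sprague Dawley day 7 animal 60 stood at 56.4 on the first component, among the virgin uteri, while the other 4 of its group lay between -40.4 and 1.79. Sprague Dawley day 10 animal 43 stood at 20.6 on the second component, against -31.5 to -25.1 in the rest of its group, and Dahl S day 10 animal M2453 at 13.4, against -28.1 to -14.9. These are the 2 day 10 arrays of the longer series. In placenta the first component, with 29.7% of the variance, placed Sprague Dawley animal 46 at -19.1, within the Dahl S range of -19.7 to -16.3, and the other 4 Sprague Dawley pools at 18.7 or above. The background control probes divided the pools in the same way, with Dahl S at 2.11 to 2.15, animal 46 at 2.11 and the other 4 at 2.18 to 2.21.

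**Figure D1:**
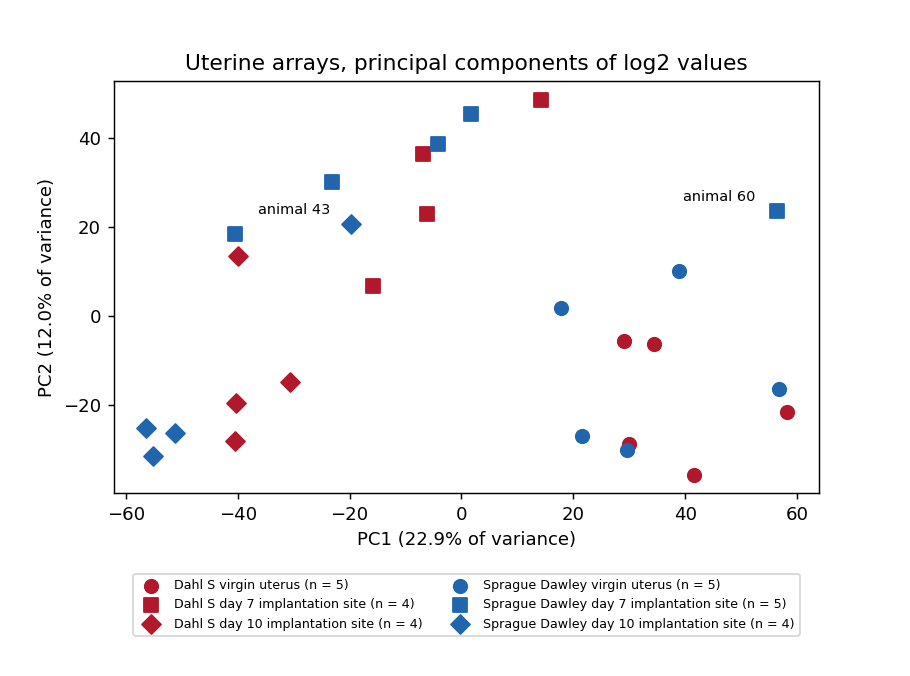
First and second principal components of the log2 values of the 27 uterine arrays, each point 1 animal, with color for strain and marker shape for stage. Virgin uteri lie at the right; Sprague Dawley day 7 animal 60, at 56.4 on the first axis, lies among them.

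In virgin uterus 4 named genes differed between the strains. Fndc7, a fibronectin type III domain gene, was lower in Dahl S by a log2 difference of -2.62 ± 0.32 (SE; 6.16-fold, n = 5 and 5, limma adjusted p = 0.000822). Rtn4ip1, a mitochondrial oxidoreductase, was also lower (-0.93 ± 0.15, adjusted p = 0.0269). Serpini1, the serine protease inhibitor neuroserpin, was higher (2.00 ± 0.35, adjusted p = 0.0454), as was Tatdn3, a putative deoxyribonuclease (0.69 ± 0.12, adjusted p = 0.0352). The remaining probe set, 17708414, has no single symbol and was lower by -1.49 ± 0.23. In all, 5 of 36495 probe sets passed, 2 higher and 3 lower, against 2271 at an unadjusted p under 0.05. The Serpini1 call ended with the background block (adjusted p = 0.0531). The count was 10 with the background block and 13 within the 8 low-background arrays. It was 13 with the number series as a block, 2 within the shorter series (3 and 3) and 1 within the longer (2 and 2). Single omissions gave between 1, without Dahl S animal M2418, and 22, without Sprague Dawley animal 67.

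Gene lists moved in virgin uterus through small shifts of members that did not pass singly. The cell cycle list was higher in Dahl S (median 0.48, 24 of 25 members above 0, camera adjusted p = 3.12e-05), with Plk1 at 0.98 ± 0.51, Ccnb2 at 0.77 ± 0.33 and Aurka at 0.48 ± 0.20. Uterine smooth muscle markers were higher (median 0.39, 11 of 12 above 0, adjusted p = 0.0095), with desmin (Des) at 0.74 ± 0.30, Tagln at 0.71 ± 0.37 and Lmod1 at 0.62 ± 0.30. The interferon list was lower (median -0.33, 20 of 22 below 0, adjusted p = 3.12e-05), with Psmb8, an immunoproteasome subunit, at -1.01 ± 0.27. The TNF and NF-kB list (median -0.23, adjusted p = 0.00994) and the immediate early and heat shock list (median -0.36, adjusted p = 0.0155) were also lower, with Nfkbia at -0.51 ± 0.19 and Junb at -0.85 ± 0.28. No member of these lists passed over all genes. Adjusted over the list alone, 1 interferon and 2 immediate early members were lower and no member of the other lists passed. Each adjusted p was 0.946 with an estimated correlation. With the background block the 5 medians were 0.39, 0.28, -0.28, -0.20 and -0.23, and within the low-background arrays 0.60, 0.39, -0.28, -0.31 and -0.36. The number series, which both strains share evenly, left the medians as they were, and within the shorter and the longer series they were 0.46 and 0.48, 0.24 and 0.53, -0.27 and -0.49, -0.28 and -0.18, and -0.35 and -0.43.

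At day 7 the genes most increased in Dahl S implantation sites were Acod1, which makes itaconate in activated macrophages and is also expressed in the uterine epithelium around implantation, and several transporters. Acod1 was higher by 3.39 ± 0.55 (SE; 10.5-fold, n = 4 and 5, adjusted p = 0.00668). The monocarboxylate transporter Slc5a8 was higher by 2.62 ± 0.51, the noradrenaline transporter Slc6a2 by 1.89 ± 0.41 and the peptide transporter Slc15a2 by 1.35 ± 0.28. The ligand Wnt7b was higher by 1.82 ± 0.32 and the cilia gene Cfap91 by 1.32 ± 0.16 (adjusted p = 0.000804). St6galnac2, Ptprr, Acot5 and Ctxn1 were higher by 1.16 to 1.25. Acod1 varied within Sprague Dawley, at 7.20 and 7.88 in animals 62 and 63 and between 4.17 and 4.31 in the other 3.

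Genes typical of mesothelium, the cell layer covering the uterus, were among those most decreased in Dahl S at day 7. Lrrn4 was lower by -2.04 ± 0.45, Gpm6a by -1.89 ± 0.39, mesothelin (Msln) by -1.85 ± 0.34, Cldn15 by -1.56 ± 0.25 and the uroplakin Upk1b by -1.56 ± 0.29, with adjusted p from 0.00668 to 0.0437. The secreted phospholipase Pla2g2a (-2.21 ± 0.50), the collagen-binding proteoglycan fibromodulin (Fmod, -1.78 ± 0.39), Psmb8 (-1.61 ± 0.28), Fndc7 (-2.29 ± 0.34) and C1h9orf85 (-2.57 ± 0.36) were also lower. In all, 123 probe sets passed, 78 higher and 45 lower, of which 55 differed at least 2-fold. With the background block 143 passed, 111 of them shared, and the calls for Ctxn1 (0.0521) and Pla2g2a (0.0591) ended. Within the 8 high-background arrays only 1 probe set passed. All 123 kept their sign there, but they had been called with these same arrays, so this is no independent support. No low-background Sprague Dawley array exists at day 7. All 9 day 7 arrays belong to the longer number series, so the strain differences are the same within it; 188 passed with the series as a block and 6 in a fit of that series alone. Leaving out Dahl S animal M2417, Dahl S animal M2429 or Sprague Dawley animal 60 gave 22, 46 or 62 calls, while a fit of the 9 day 7 arrays alone gave 5.

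The largest list shift at day 7 was a rise of uterine smooth muscle markers in Dahl S (median 0.99, camera adjusted p = 2.08e-06). None of the 12 members passed over all genes and 9 were higher adjusted over the list alone, among them Lmod1 at 1.13 ± 0.32, Mylk at 1.05 ± 0.28 and Myh11 at 0.96 ± 0.30. Macrophage and dendritic cell markers were lower, all 18 below 0 (median -0.43, adjusted p = 0.000229), with Lyz2 at -1.31 ± 0.41, Cd163 at -0.58 ± 0.28 and Ptprc at -0.48 ± 0.20, none passing singly or over the list alone. Fat tissue markers were lower (median -0.57, adjusted p = 0.00154; 6 lower and 1 higher of 12 adjusted over the list alone), with Adipoq at -2.66 ± 0.76. The MHC list (median -0.28, adjusted p = 0.00772; 3 of 16 lower adjusted over the list alone) had RT1-Db1 at -1.29 ± 0.33 and RT1-CE5 at -0.93 ± 0.21. Whether the probes of the MHC genes bind the sequences of both strains alike was not examined. The oxidative stress list was lower too (median -0.28, adjusted p = 0.0231), with Sod3 at -0.68 ± 0.22 and Txnrd1 at -0.43 ± 0.16. With an estimated correlation the adjusted p was 0.789 for the smooth muscle and oxidative stress lists and 0.828 for the other 3. In the order given, the medians were 0.92, -0.49, -0.61, -0.30 and -0.25 with the background block and 0.97, -0.41, -0.66, -0.25 and -0.30 within the high-background arrays. Without Sprague Dawley animals 60 and 43 they were 0.64, -0.26, -0.66, -0.04 and -0.19, and without animal 60 alone 3 of the 5 list calls were kept.

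**Figure D2:**
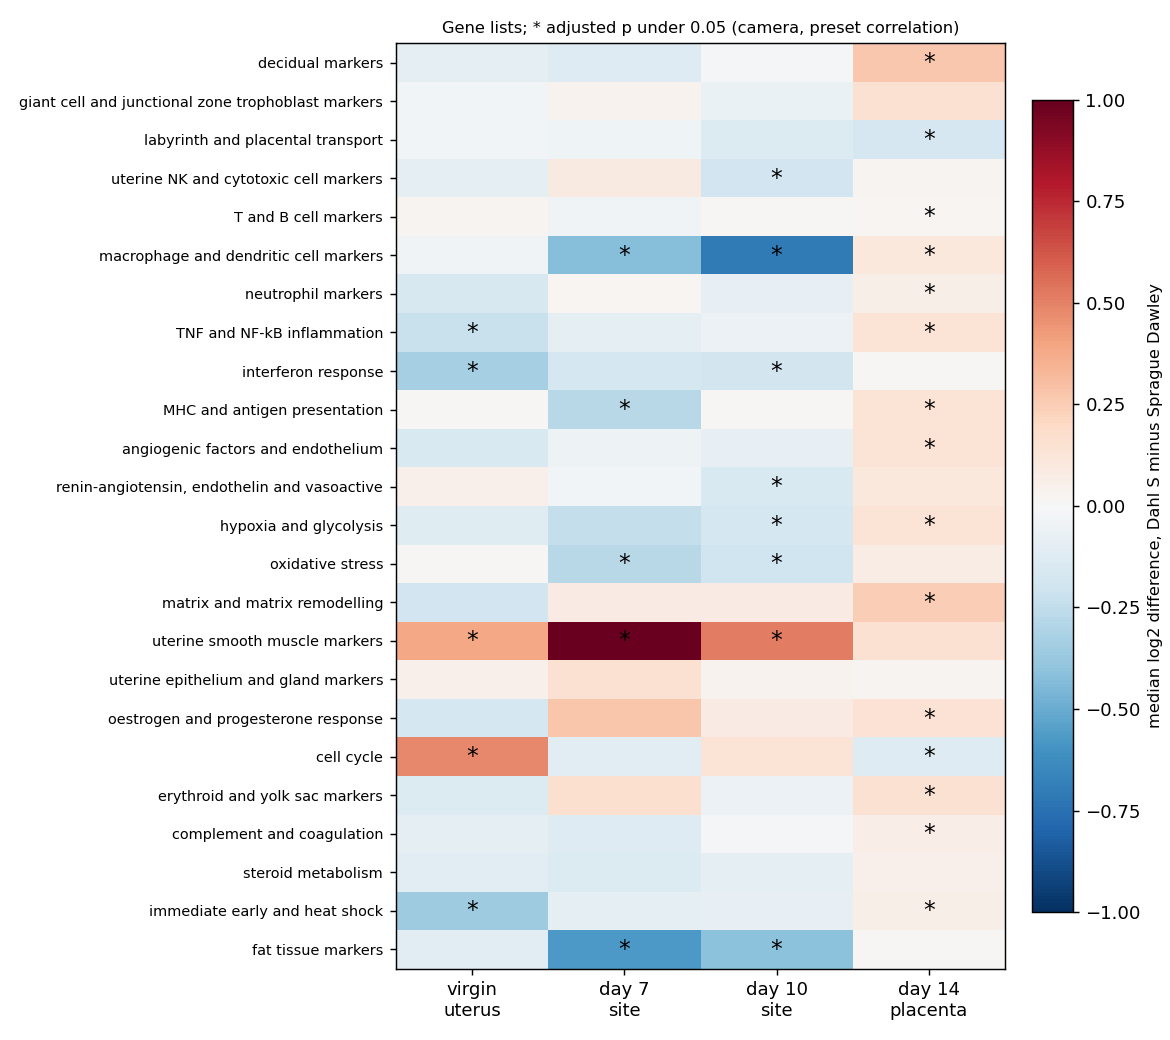
Median log2 difference (Dahl S minus Sprague Dawley) of the members of each of 24 gene lists at the 4 stages, with red for higher and blue for lower in Dahl S. An asterisk marks a camera adjusted p under 0.05 at the preset correlation; smooth muscle markers reach 0.99 at day 7 and macrophage markers -0.71 at day 10.

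At day 10 mesothelial genes were again among those most decreased in Dahl S sites, with 2 hemoglobin genes. Lrrn4 was lower by -2.80 ± 0.47 (SE; 6.96-fold, n = 4 and 4, adjusted p = 0.00981), Upk3b by -2.30 ± 0.45, Gpm6a by -2.18 ± 0.41 and Upk1b by -1.77 ± 0.30. The globins Hba-a1 (-2.77 ± 0.37, adjusted p = 0.00125) and Hbb-b1 (-2.44 ± 0.46) were lower. F13a1, the coagulation factor XIII subunit carried by resident macrophages, was lower by -1.80 ± 0.35. The prostaglandin-degrading enzyme Hpgd (-1.85 ± 0.33), the sulfate-donor synthase Papss2 (-1.65 ± 0.28) and Cmahp (-1.88 ± 0.24) completed the 10 largest decreases. Rises were smaller. The cytochrome Cyp2e1 was higher by 1.70 ± 0.25 (adjusted p = 0.00319), the zinc transporter Slc30a3 by 1.12 ± 0.20, the cytokine Mif by 0.73 ± 0.13 and the kinase Hipk2 by 0.76 ± 0.14. Chchd4l1, Tatdn3, Farp1, Fbxl19 and Srrm2 were higher by 0.46 to 0.77.

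In all, 66 probe sets passed at day 10, 36 higher and 30 lower, of which 33 differed at least 2-fold. This balance depended on the processing. With 1 probe set per gene 10 were higher and 33 lower, without animal 43 the split was 55 and 90, and in a fit of the 8 day 10 arrays alone 9 and 17. With the background block 83 passed, 65 of them shared. All 66 kept their sign within the 6 low-background arrays, where 247 passed, and in the comparison of 1 high-background array per strain. The 66 had been called with these same arrays, so the kept signs are no independent support. The day 10 arrays divide in the same way by number series, with 79 calls with the series as a block and 210 in a fit of the shorter series alone. Without Sprague Dawley animal 43, 145 passed, and leaving out any other animal gave between 29, without Dahl S animal M2444, and 50.

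Macrophage and dendritic cell markers were lower in Dahl S at day 10, all 18 below 0 (median -0.71, camera adjusted p = 2.89e-08), with Cd163 at -1.16 ± 0.29, Cd68 at -1.09 ± 0.38 and Csf1r at -1.01 ± 0.26. None passed over all genes and 2 were lower adjusted over the list alone. Uterine NK and cytotoxic markers were lower (median -0.19, 14 of 17 below 0, adjusted p = 0.00147), with Gzmc at -0.90 ± 0.37 and Gzmb at -0.81 ± 0.38. The oxidative stress list was lower (median -0.20, adjusted p = 0.00583) and held the only member that passed over all genes, the extracellular superoxide dismutase Sod3 (-1.28 ± 0.23, adjusted p = 0.01). Fat (median -0.41, adjusted p = 0.00583), interferon (-0.18, adjusted p = 0.0238), hypoxia and glycolysis (-0.18, adjusted p = 0.0354) and renin-angiotensin, endothelin and vasoactive lists (-0.15, adjusted p = 0.0469) were lower and smooth muscle markers higher (0.51, adjusted p = 0.0354). In the interferon list Psmb8 was at -1.27 ± 0.30, in the vasoactive list Nppb at -1.06 ± 0.44, and 1 interferon member and Sod3 were lower adjusted over the list alone. With an estimated correlation the adjusted p values were 0.487 for the macrophage and NK lists, 0.448 for the oxidative stress and vasoactive lists and 0.66 for the other 4.

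These day 10 list medians were not alike in the background sets, which at day 10 are also the number series. The high-background side is a single array per strain and no test between the sets was run, so a difference between them cannot be concluded. The macrophage median was -1.13 within the low-background arrays (3 and 3) but 0.69 between the single high-background arrays, of which the Sprague Dawley one is animal 43, and the NK median was -0.36 and 0.17. The smooth muscle median was 0.41 and 0.96, fat -0.34 and -0.52, oxidative stress -0.14 and -0.30, hypoxia -0.11 and -0.31, interferon -0.06 and -0.36, and vasoactive -0.12 and -0.07. Either block left the 8 medians as they were, because the sets are balanced at day 10. Without animal 43, 4 of the 8 list calls were kept.

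**Figure D3:**
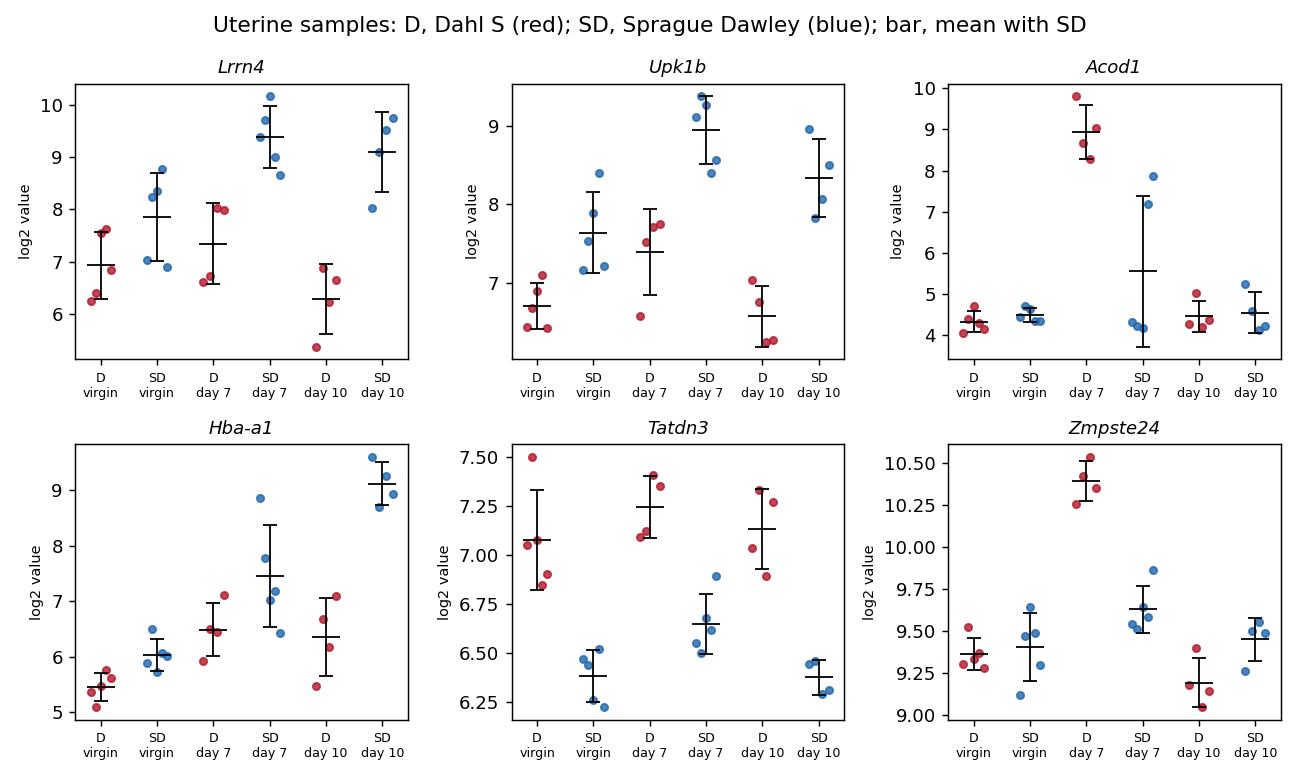
Log2 values of 6 genes in each uterine sample, with points for single animals, horizontal bars for group means and whiskers for SD. Dahl S lies below Sprague Dawley for Lrrn4 and Upk1b at days 7 and 10 and for Hba-a1 at day 10, and above it for Tatdn3 at every stage, while Acod1 and Zmpste24 are raised in Dahl S at day 7.

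In day 14 placenta, trophoblast genes changed in both directions in Dahl S. The pregnancy-specific glycoprotein Psg29 was lower by -1.73 ± 0.22 (SE; 3.32-fold, n = 5 and 5, adjusted p = 0.00784). The placental cathepsin Ctsm (-1.26 ± 0.22), the spongiotrophoblast marker Tpbpa (-1.24 ± 0.26, adjusted p = 0.0483) and the prolactin family member Prl2b1 (-1.20 ± 0.19) were lower, while another member, Prl7a4, was higher by 1.26 ± 0.17. C1h9orf85 (-1.87 ± 0.30), Rps16 (-1.10 ± 0.14), Taf7l (-0.98 ± 0.16), the matrix gene Fbln1 (-0.87 ± 0.15), Ocm (-0.81 ± 0.12) and the pericyte gene Rgs5 (-0.80 ± 0.08, adjusted p = 0.00135) were also lower. Complement C3 was higher by 1.17 ± 0.21, the chemokine Cxcl6 by 1.10 ± 0.22, olfactomedin 4 (Olfm4) by 1.10 ± 0.13, lipocalin (Lcn2) by 1.08 ± 0.19, lactoperoxidase (Lpo) by 1.03 ± 0.11 and Ly6i by 1.42 ± 0.20. Sned1, Rimklb and neuropeptide Y (Npy) were higher by 1.28 ± 0.20, 1.21 ± 0.16 and 1.09 ± 0.13.

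Of 36495 probe sets, 395 passed in placenta, 165 higher and 230 lower, and only 28 differed at least 2-fold. Without Sprague Dawley animal 46 the count was 2698, among them all 395, with strain and background then fully joined, whereas leaving out any of the other 9 animals gave between 67, without Dahl S animal M2447, and 266. Without Sprague Dawley animal 50 or 64 slightly more were higher than lower, 84 and 78 or 141 and 125. The count was 198 without the trend and 122 with all 37 arrays in 1 fit, of which 89 were higher and 33 lower.

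Background went with strain in placenta, and few single calls held when it was taken into account. With the background division as a block, which leaves pool 46 against the Dahl S pools, 6 probe sets passed, 4 of them shared, among them Tatdn3 (0.88 ± 0.07) and Cops9 (-0.68 ± 0.07). With the background level as a covariate 8 passed, all shared, among them these 2 genes, Prl8a2 (0.63 ± 0.07) and Ceacam1 (-0.62 ± 0.07). All 395, which were called with pool 46 among the Sprague Dawley pools, kept their sign under both. With the block Prl7a4 was at 1.39 ± 0.31, Olfm4 at 1.04 ± 0.24, Npy at 1.18 ± 0.24, Psg29 at -1.26 ± 0.34 and Rps16 at -1.13 ± 0.24, none passing, while Cxcl6 was at 0.40 ± 0.30, Lcn2 at 0.38 ± 0.23, Sned1 at 0.43 ± 0.17, Tpbpa at -0.61 ± 0.40 and Prl2b1 at -0.57 ± 0.24. The 2698 probe sets called without pool 46 placed that pool at 0.0692 between the Dahl S pools, 0, and the other Sprague Dawley pools, 1.

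**Figure D4:**
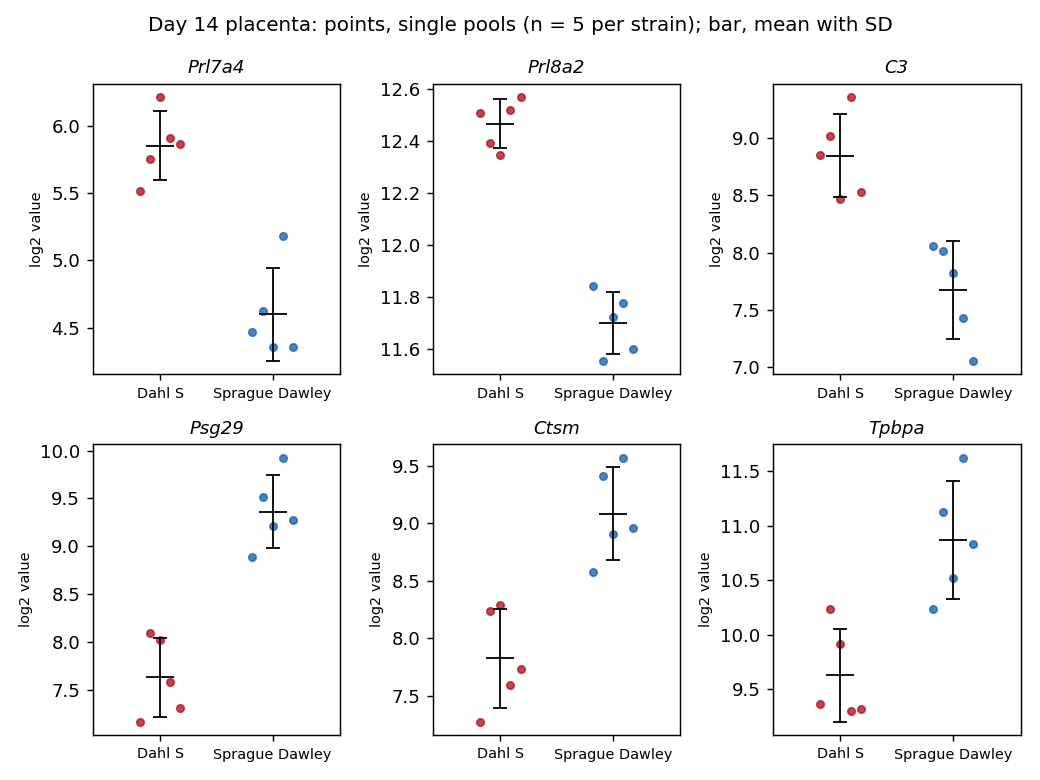
Log2 values of 6 genes in each of the 10 placental pools, with horizontal bars for means and whiskers for SD. Prl7a4, Prl8a2 and C3 are higher in Dahl S, with differences of 1.26, 0.77 and 1.17, and Psg29, Ctsm and Tpbpa lower, with -1.73, -1.26 and -1.24.

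By list, decidual markers and several immune lists were higher in Dahl S placenta, the latter by small medians, and proliferation and labyrinth markers were lower. None of the 15 list calls held with an estimated correlation, where the adjusted p ran from 0.0901 to 0.327. The background block kept 2 of the 15, neutrophil markers and MHC, and reversed the camera direction of 3. List medians changed sign with the block in further lists, as given below. With the background level as a covariate 10 calls were kept. The cell cycle list was lower with 24 of 25 members below 0 (median -0.13, camera adjusted p = 1.02e-05); none passed over all genes and 8 were lower adjusted over the list alone, such as Aurkb (-0.28 ± 0.07) and Top2a (-0.24 ± 0.06). Labyrinth and transport genes were lower (median -0.17, adjusted p = 0.0201; 4 lower and 1 higher of 20 over the list alone), with the monocarboxylate transporter Slc16a1 at -0.36 ± 0.05 passing over all genes and Ctsq at -0.90 ± 0.19. Decidual markers were higher (median 0.27, adjusted p = 0.00433; 4 higher and 1 lower of 17 over the list alone), led by decidual prolactin-related protein Prl8a2 (0.77 ± 0.06, adjusted p = 0.000696). For these 3 lists the adjusted p with an estimated correlation was 0.242, 0.327 and 0.23. Their medians were 0.01, -0.03 and -0.07 with the background block and -0.05, -0.03 and 0.17 with the covariate, so the cell cycle and decidual directions were not kept with the block. The giant cell and junctional zone list did not pass (adjusted p = 0.129), with 5 of 20 members higher and 5 lower adjusted over the list alone.

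Immune lists in placenta were higher by small medians. Macrophage and dendritic cell markers (median 0.11, adjusted p = 0.000572; 5 of 18 higher over the list alone) included the leukocyte antigen Ptprc (0.64 ± 0.10), and neutrophil markers (0.06, adjusted p = 0.00182; 4 of 13) included Lcn2 and S100a9 (0.63 ± 0.12). The TNF and NF-kB list (0.14, adjusted p = 0.000465; 4 higher and 1 lower of 22) included the receptor Tlr4 (0.92 ± 0.18). T and B cell markers (0.02, adjusted p = 0.0202; 2 of 16) included Cd79a (0.81 ± 0.14). In the MHC list (0.14, adjusted p = 0.0102) the array signal of the class II gene RT1-Bb was higher by 0.97 ± 0.13 and that of the class I gene RT1-CE5 lower by -0.61 ± 0.11, with probe binding in the 2 strains not examined. Complement and coagulation genes (0.07, adjusted p = 0.00323; 5 higher and 1 lower of 18) included Serpine2 (0.96 ± 0.13) and C3. In the order given, the adjusted p of these 6 lists with an estimated correlation was 0.0901, 0.167, 0.113, 0.242, 0.23 and 0.102. The medians were 0.05, 0.18, 0.05, 0.09, 0.19 and -0.04 with the background block and 0.09, 0.09, 0.11, 0.04, 0.13 and 0.07 with the covariate, and Tlr4 was at 0.28 ± 0.22 with the block.

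Matrix genes (median 0.25, adjusted p = 1.32e-05; 7 higher and 2 lower of 22 over the list alone) held Lox at 1.75 ± 0.43, which did not pass over all genes, and Col4a2, which was lower (-0.38 ± 0.06). The angiogenic and endothelial list was higher (0.14, adjusted p = 0.000432; 7 higher and 1 lower of 19), with Corin, the protease that activates atrial natriuretic peptide, higher by 0.93 ± 0.18 and the endothelial cadherin Cdh5 lower by -0.18 ± 0.03. Hypoxia and glycolysis (0.14, adjusted p = 0.000204; 4 higher and 1 lower of 18), oestrogen and progesterone response (0.14, adjusted p = 0.000432; 1 of 15, C3), erythroid and yolk sac (0.15, adjusted p = 9.75e-05; 7 of 16, among them Apoa4 at 1.83 ± 0.48) and immediate early lists (0.06, adjusted p = 0.027; 3 higher and 1 lower of 13) were also higher. The estimated correlation gave these 6 lists an adjusted p of 0.167, 0.23, 0.167, 0.113, 0.23 and 0.242. Their medians were -0.12, -0.04, 0.09, -0.03, -0.18 and 0.03 with the background block and 0.11, 0.05, 0.16, 0.17, 0.08 and 0.10 with the covariate, and Corin was at 0.26 ± 0.21 with the block. Without animal 46, 13 of the 15 list calls were kept.

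Of the 10 genes taken from the preeclampsia literature, 9 were measured by a probe set with a single symbol, and none passed between the strains at any stage. Placental growth factor (Pgf) had the largest difference, 1.94 ± 0.66 at day 7 (adjusted p = 0.205), with 1.17 ± 0.70 at day 10, 0.98 ± 0.34 in placenta (adjusted p = 0.198; -0.31 ± 0.38 with the background block) and -0.29 ± 0.62 in virgin uterus. Vegfa differed by 0.02 ± 0.06 and its receptor gene Flt1 by 0.28 ± 0.14 (adjusted p = 0.365) in placenta, with the soluble form of the receptor not measured apart.

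A small set of genes separated the strains by array signal at several stages. Whether the probes bind the sequences of both strains alike was not examined for these or any other genes. Tatdn3 passed at all 4, higher in Dahl S by 0.69, 0.60, 0.76 and 0.59. Cops9, a signalosome subunit, passed at day 7, day 10 and in placenta, lower by -0.51 ± 0.11, -0.78 ± 0.12 and -0.58 ± 0.05, and was at -0.26 in virgin uterus. Of the 5 virgin calls, 4 were shared in direction at day 7, where 0.008 would be expected of independent lists. Days 7 and 10 shared 7 calls (0.114 expected), and day 7 and placenta 11 (0.636 expected) with 1 in the opposite direction. The uterine comparisons come from 1 fit with a shared estimate of spread, so their lists are not independent. The expected counts are therefore only a guide.

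From virgin uterus to day 7, both strains gained decidual genes and lost epithelial genes. Igfbp1, a classical product of decidualizing stroma, rose by 4.45 ± 0.57 in Sprague Dawley (n = 5 and 5, adjusted p = 0.000474) and 5.48 ± 0.60 in Dahl S (n = 4 and 5, adjusted p = 5.48e-06). The retinoic acid hydroxylase Cyp26a1 rose by 3.86 ± 0.61 and 5.08 ± 0.65. Erbb4, Serpinb12, Atp6v0a4 and Selenbp1 rose by 2.76 to 2.98 in Sprague Dawley, and Acod1 (4.62 ± 0.55), Igfbp3 (4.36 ± 0.48), Pgf (3.98 ± 0.66) and Slc5a8 (3.97 ± 0.51) were among the largest rises in Dahl S. The epithelial protease Mmp7 fell by 5.17 ± 1.07 and 5.15 ± 1.13, A2ml1 by 3.80 ± 0.86 and 6.15 ± 0.91, and the epithelial ligand Wnt7a by 2.40 ± 0.36 and 3.21 ± 0.39. Trappc3l fell in both strains, Plekhs1, Fam3b and Far2 in Sprague Dawley by 2.99 to 3.12, and Gabrp, Cd8a and Alox12 in Dahl S by 3.55 to 5.58. Sprague Dawley animal 60 held back these changes, and without it they were -6.69 for Mmp7, -5.13 for A2ml1, -4.33 for Trappc3l, -3.81 for Plekhs1, -3.90 for Fam3b, -3.60 for Far2, 4.76 for Cyp26a1, 3.64 for Erbb4 and 3.61 for Serpinb12. Without Dahl S animal M2417 the rise of Pgf was 4.72.

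Decidual markers rose from virgin to day 7 in both strains (medians 0.72 in Sprague Dawley, camera adjusted p = 0.000553, and 0.52 in Dahl S, adjusted p = 0.00524), and epithelial and gland markers fell (-0.46, adjusted p = 0.000553, and -0.45, adjusted p = 0.000252). Interferon (-0.51, adjusted p = 7.16e-08, and -0.47, adjusted p = 7.95e-05) and MHC lists (-0.29, adjusted p = 0.0106, and -0.50, adjusted p = 1.4e-06) fell, with Mx2 lower by -1.66 ± 0.29 in Sprague Dawley and Cd74 by -1.69 ± 0.30 in Dahl S. Members of the interferon list went both ways in Dahl S, where Rsad2 was higher by 1.20 ± 0.26 and Rig1 lower by -0.92 ± 0.20. In Dahl S smooth muscle markers rose (0.76, adjusted p = 0.000125; Kcnmb1 1.82 ± 0.49) and macrophage markers fell (-0.61, adjusted p = 7.95e-05; Lyz2 -1.96 ± 0.41). In Sprague Dawley complement (0.67, adjusted p = 0.0134; F5 2.02 ± 0.38), fat (0.52, adjusted p = 0.00896; Lpl 1.93 ± 0.30), cell cycle (0.49, adjusted p = 0.044) and vasoactive lists (0.11, adjusted p = 0.031; Agtr1a 1.25 ± 0.28) rose and the immediate early list fell (-0.45, adjusted p = 0.0106). Passing in 1 strain alone is not a difference between the strains. The Dahl S medians of these lists were 0.10, 0.12, -0.28, 0.13 and -0.09, so the vasoactive median was alike in both strains. The Sprague Dawley medians were 0.28 for smooth muscle and -0.30 for macrophage markers. The strain difference in this step did not pass for the complement, vasoactive and immediate early lists. Adjusted over the list alone, 6 decidual members rose and 12 interferon and 6 epithelial members fell in Sprague Dawley, and 4, 10 and 5 did so in Dahl S. With an estimated correlation the adjusted p was 0.78 for the Sprague Dawley cell cycle list, 0.482 for the other 8 Sprague Dawley lists and 0.484 for all 6 in Dahl S.

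These list shifts kept their direction with both blocks and within sets of arrays. In Sprague Dawley the medians for decidual, epithelial, interferon, MHC, complement, fat, cell cycle, vasoactive and immediate early lists were 0.76, -0.49, -0.45, -0.19, 0.77, 0.59, 0.52, 0.19 and -0.46 with the number series as a block. The background block gave 0.76, -0.58, -0.54, -0.24, 0.78, 0.53, 0.70, 0.25 and -0.54. Within the longer series, whose Sprague Dawley arrays here are the high-background ones, they were 0.74, -0.24, -0.42, -0.10, 0.84, 0.62, 0.20, 0.23 and -0.40. In Dahl S the medians for decidual, epithelial, interferon, MHC, smooth muscle and macrophage lists were 0.41, -0.54, -0.47, -0.42, 0.79 and -0.40 with the series block and 0.51, -0.47, -0.56, -0.43, 0.85 and -0.39 with the background block. They were 0.53, -0.55, -0.33, -0.35, 0.51 and -0.42 within the longer series and 0.84, -0.56, -0.52, -0.51, 0.67 and -0.70 within the low-background arrays.

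In Sprague Dawley 868 probe sets changed from virgin to day 7, 442 up and 426 down, and in Dahl S 1171, 564 up and 607 down. The 2 sets shared 321 changes in the same direction and 1 in the opposite one, with 13.9 expected of independent lists. Both come from 1 fit with a shared estimate of spread, so they are not independent and 13.9 is only a guide. Background differed between virgin and day 7 arrays, and with the background block 352 and 512 passed. The block ended the call of A2ml1 in Sprague Dawley (adjusted p = 0.0633) and of Lyz2 (0.0822) and Rsad2 (0.144) in Dahl S. With the number series as a block 489 and 734 passed, and the calls of A2ml1 (0.0652) and Rsad2 (0.0537) ended. All 868 and all 1171 kept their sign within the longer series, where 40 (5 and 2 arrays) and 124 (4 and 2) passed. Within the high-background arrays none passed in Sprague Dawley (5 and 2 arrays), and all 868 kept their sign. These probe sets had been called with the same arrays among others, so the kept signs are no independent support. The Sprague Dawley count was 1766 without animal 60, 282 without virgin animal 68 and 2 when only the groups compared were fitted; in Dahl S it fell to 689 without animal M2455.

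From day 7 to day 10, Gzmc, A2m and S100a4 rose in both strains. Granzyme C (Gzmc), a product of uterine NK cells, rose by 4.97 ± 0.35 in Sprague Dawley (n = 4 and 5, adjusted p = 1.13e-08) and 3.76 ± 0.37 in Dahl S (n = 4 and 4, adjusted p = 2.36e-06). The decidual protease inhibitor A2m rose by 3.72 ± 0.55 and 4.09 ± 0.58, and S100a4 by 3.52 ± 0.41 and 3.88 ± 0.43. Prl8a2 (4.85 ± 1.29), Orm1 (4.71 ± 0.94) and Clic5 (3.59 ± 0.44) rose in Sprague Dawley, with Prl8a2 at 8.46 and 10.01 in day 7 animals 62 and 63 and at 2.56 to 2.90 in the other 3, and Padi2 (3.65 ± 0.38), osteopontin (Spp1, 3.53 ± 0.75) and Mfap5 (2.93 ± 0.42) in Dahl S. Leaving out single animals moved the Prl8a2 rise between 4.04, without animal 43, and 6.02, without animal 63 or 57, and its call ended without animal 55, 60, 45, 49, 59 or 43. Orm1 ranged from 3.87, without animal 43, to 5.41, without animal 57, and was 5.33 without animal 60, and Clic5 was 2.92 without animal 43. The Dahl S genes raised at day 7 came down, Acod1 by -4.48 ± 0.58, Slc5a8 by -3.93 ± 0.54, Slc15a2 by -3.03 ± 0.30 and Wnt7b by -2.32 ± 0.33, with Pde1c and F5 at -2.41 and -2.40. In Sprague Dawley the largest falls were Cpm and Elapor1 (each 3.99-fold), Cldn8, Tspan1, Ano4 and Slc15a2 (-1.60 ± 0.28).

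Between days 7 and 10 macrophage (0.65, camera adjusted p = 2.51e-05, and 0.53, adjusted p = 0.000347), hypoxia (0.50, adjusted p = 0.000756, and 0.25, adjusted p = 0.000586), matrix (0.73, adjusted p = 0.000184, and 0.52, adjusted p = 9.3e-05), cell cycle (0.51, adjusted p = 0.00229, and 0.86, adjusted p = 4.26e-07) and TNF lists (0.16, adjusted p = 0.0197, and 0.10, adjusted p = 0.0207) rose in Sprague Dawley and Dahl S. Epithelial markers fell in both (-0.64, adjusted p = 0.00229, and -0.47, adjusted p = 0.0415), with Cldn3 at -1.30 ± 0.26 and -1.47 ± 0.28. Adjusted over the list alone, 8 macrophage, 6 hypoxia and 7 matrix members rose in Sprague Dawley, and 1, 4 and 5 in Dahl S. Examples were Cd163 (1.11 ± 0.28), Ccl2 (1.44 ± 0.44), Rrm2 (2.95 ± 0.74) and the matrix protease Mmp3 (2.04 ± 0.47) in Sprague Dawley, and the hypoxia regulator Epas1 in both (1.61 ± 0.41 and 1.68 ± 0.43). Mmp3 was at 1.23 without animal 43 and Rrm2 at 2.23 without animal 60. NK and cytotoxic markers (median 0.22, adjusted p = 2.51e-05; 6 of 17 passed over all genes) and the erythroid list (0.12, adjusted p = 0.0471) passed in Sprague Dawley, with perforin (Prf1) at 2.40 ± 0.38, Gzmb at 2.93 ± 0.36 and Hba-a1 at 1.66 ± 0.35. With an estimated correlation the adjusted p of these lists ran from 0.23 to 0.649 in Sprague Dawley and from 0.16 to 0.601 in Dahl S. The decidual list did not pass for this step in either strain (adjusted p = 0.0602 and 0.103), nor the NK list in Dahl S (adjusted p = 0.0711). The steroid metabolism and giant cell lists passed in none of the 10 comparisons.

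Several of the Sprague Dawley list shifts between days 7 and 10 did not hold within the longer series, where animal 43 is the only day 10 array. There the macrophage median was -0.45, cell cycle -0.66 and NK -0.01, while hypoxia was 0.59, matrix 0.14, TNF 0.38, epithelium -0.12 and erythroid 0.43. With the series as a block these were 0.40, 0.42, 0.20, 0.51, 0.70, 0.15, -0.51 and 0.10, and with the background block 0.41, 0.28, 0.23, 0.50, 0.61, 0.21, -0.41 and 0.12. In Dahl S the macrophage, hypoxia, matrix, cell cycle, TNF and epithelial medians were 0.20, 0.34, 0.44, 0.77, 0.17 and -0.43 with the series block and 0.31, 0.35, 0.43, 0.77, 0.16 and -0.39 with the background block. Within the longer series they were 0.66, 0.39, 0.62, 1.19, 0.22 and -0.38, within the low-background arrays 0.41, 0.28, 0.39, 0.27, 0.18 and -0.26, and within the high-background ones 0.69, 0.39, 0.64, 1.37, 0.17 and -0.39.

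In Sprague Dawley 2296 probe sets changed from day 7 to day 10, 886 up and 1410 down, and in Dahl S 598, 253 up and 345 down. They shared 302 in direction and 1 opposite, with 19.5 expected of independent lists, which lists from 1 fit are not. Quantile normalization turned the Sprague Dawley balance to 1000 up and 1014 down, and the background block to 329 up and 286 down. A fit of the Dahl S day 7 and day 10 arrays alone gave 904 up and 753 down. With the background block 615 and 231 passed. The block ended the Sprague Dawley calls of Prl8a2 (adjusted p = 0.087), Elapor1 (0.0636), Cldn8 (0.0976), Tspan1 (0.165), Cd163 (0.165), Ccl2 (0.204), Epas1 (0.109), Cldn3 (0.0761) and Rrm2 (0.0962), and the Dahl S call of Epas1 (0.117). With the number series as a block 868 and 201 passed. That block ended the Sprague Dawley calls of Prl8a2 (0.0607), Tspan1 (0.0887), Cd163 (0.131), Ccl2 (0.204), Epas1 (0.065) and Cldn3 (0.0525), and the Dahl S calls of Spp1 (0.0875), Pde1c (0.0559), Epas1 (0.132) and Cldn3 (0.0639). In fits of the longer series alone 957, 754 up and 203 down (1 and 5 arrays), and 18 (1 and 4) passed, with 2232 of 2296 and all 598 keeping their sign. Within the high-background arrays 581 passed in Sprague Dawley (1 and 5 arrays), 502 up and 79 down, with 2232 of 2296 keeping their sign, and 4 in Dahl S (1 and 3), with 98 within the low-background ones (3 and 1) and all 598 keeping their sign in both. The calls had been made with these arrays among others, so the kept signs are no independent support. The Sprague Dawley count ran from 921 without animal 49 to 3639 without animal 43, and the Dahl S count fell to 221 without animal M2446.

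Whether the strains differed in these steps was tested directly. No probe set passed for the step to day 7 (limma, smallest adjusted p = 0.156), with 2168 at an unadjusted p under 0.05. The 5 named genes with the smallest p were Cfap91 (a strain difference in the step of 1.31 ± 0.22), Zmpste24 (0.80 ± 0.14), Or2g7 (1.11 ± 0.21), Wnt7b (2.28 ± 0.44) and Fancg (-0.76 ± 0.16). For the step to day 10, 2 genes passed, and 2012 probe sets had an unadjusted p under 0.05. Zmpste24, the protease that matures lamin A, fell from 10.39 ± 0.12 to 9.20 ± 0.15 (SD) in Dahl S and from 9.63 ± 0.14 to 9.45 ± 0.13 in Sprague Dawley (difference -1.02 ± 0.15, adjusted p = 0.02). The mast cell protease gene Mcpt10 went from 2.25 ± 0.09 to 2.21 ± 0.13 in Dahl S and from 2.28 ± 0.14 to 3.42 ± 0.35 in Sprague Dawley. The first 3 of these means lie at the level of the background control probes, 1.84 to 2.30 in the uterine arrays, so the size of its difference is not known. Both passed with the background block and with the number series as a block, and both calls ended in a fit of only the groups compared and with a block of the running numbers that day 7 and day 10 arrays share. Fits of the high-background arrays and of the longer series, which each hold 1 day 10 array per strain, gave 131 and 231 calls, and 1 call for the step to day 7 in the longer series; the count without a single animal ran from 0 to 9, and it was 46 with all 37 arrays in 1 fit.

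Lists also differed between the strains in these steps. In the step to day 7 the cell cycle (median -0.80, camera adjusted p = 0.000542), macrophage (-0.40, adjusted p = 0.0083), MHC (-0.27, adjusted p = 0.0083) and fat lists (-0.52, adjusted p = 0.0083) moved lower in Dahl S than in Sprague Dawley and smooth muscle markers higher (0.47, adjusted p = 0.0236). In the step to day 10 the NK (-0.34, adjusted p = 0.00175), erythroid (-0.30, adjusted p = 0.00462) and smooth muscle lists (-0.44, all 12 members below 0, adjusted p = 0.0228) moved lower and the MHC list higher (0.24, adjusted p = 0.0228). With the background block the medians were -0.75, -0.36, -0.25, -0.50 and 0.49 for day 7 and -0.32, -0.30, -0.39 and 0.31 for day 10, and the number series block left them as they were. Within the longer series they were -0.59, -0.34, -0.17, -0.55 and 0.36 for day 7 and 0.01, -0.47, 0.11 and 0.55 for day 10, so the NK and smooth muscle shifts did not keep their direction there. Within the high-background arrays the day 10 values were 0.05, -0.45, 0.09 and 0.61. Step medians without Sprague Dawley day 7 animal 60, which resembled virgin uterus, are not given. For the 5 day 7 lists in that order, the strain medians at day 7 itself were -0.11, -0.43, -0.28, -0.57 and 0.99. Without animals 60 and 43 they were -0.43, -0.26, -0.04, -0.66 and 0.64, so little of the MHC difference was left. The adjusted p with an estimated correlation was 0.791 for all 5 day 7 lists, 0.868 for the NK and erythroid lists and 0.965 for the other 2. Over all genes no member passed, and adjusted over the list alone 1 MHC and 1 fat member passed at day 7 and 3 erythroid members, all lower, at day 10.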

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

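All tests of explanations below, the other splits of the arrays, and the list of mesothelial markers were chosen only after the results were seen, and 1 of the tests was changed after a first form had been seen to decide nothing. A count for placental pool 46 was changed in the same way and then dropped as a test.

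Single animals were far from the rest of their group in 29 of 436 gene and group pairs, where chance alone gives about 22. Sprague Dawley day 7 animal 60 accounted for 8 of them. It read Mmp7 at 12.67, A2ml1 at 12.53, Trappc3l at 9.73, Fam3b at 9.73, Plekhs1 at 9.07, Wnt7a at 7.82, Orm1 at 7.86 and Synpo2 at 7.29. Dahl S virgin animal M2435 accounted for 5, with Gabrp at 10.69, Trappc3l at 10.31, Wnt7a at 8.44, Stat2 at 8.33 and Rsad2 at 6.35, and Dahl S day 7 animal M2446 for 3, with Cdk1 at 5.47, Trappc3l at 4.81 and C1h9orf85 at 3.90. Among Sprague Dawley animals, day 10 animal 43 stood out for F13a1 at 7.76 and Cd163 at 5.98, day 7 animal 55 for Lpl at 10.39 and Sod3 at 9.43, and day 7 animal 63 for Gzmb at 6.51 and Cfap91 at 4.79. Single cases were virgin animal 67 for A2ml1 at 12.64, day 10 animal 49 for Adipoq at 5.70, and placental pool 46 for Tatdn3 at 7.10. In Dahl S they were virgin animal M2438 for Ccnb2 at 9.62, day 7 animal M2429 for Fndc7 at 5.41, and day 10 animals M2453 for Cops9 at 10.06 and M2436 for Epas1 at 11.17.

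A test of the difference between the strains' gestation steps picked out Mcpt10 (-1.18) and Zmpste24 (-1.02) for the step to day 10, but Mcpt10 was at the level of the background control probes in 3 of the 4 groups, so the size of its difference is not known. It picked out the lists for NK cells (-0.34), MHC (0.24), smooth muscle (-0.44) and erythroid genes (-0.30) there, and for macrophages (-0.40), MHC (-0.27), smooth muscle (0.47), cell cycle (-0.80) and fat (-0.52) in the step to day 7.

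Other divisions of the same arrays were tried to see how often chance gives as many calls. As many calls as with the real labels came in 4 of 100 divisions for virgin uterus, 3 of 100 for day 7, 1 of 35 for day 10 and 1 of 100 for placenta, the real one included. For the gestation steps the figures were 1 of 100 (day 7, Sprague Dawley), 1 of 100 (day 7, Dahl S), 4 of 100 (day 10, Sprague Dawley) and 1 of 35 (day 10, Dahl S). For the strain difference in the step to day 10 the figure was 5 of 100, with 2 real calls and up to 141 in another division, so chance was not excluded. For the step to day 7 it was 100 of 100, which follows from the real count of 0 and tests nothing. Some divisions gave far more calls than the real labels, with 239 in virgin uterus against 5, 1341 at day 7 against 123 and 3660 in the Sprague Dawley step to day 10 against 2296, and the last 2 put animal 60 with animals 45 and 55 on 1 side. In that step all 4 animals on this side belong to the longer number series, and the real labels gave 868 calls with the series as a block. Animals 62 and 63, on the other side, belong to the longer series too. All day 7 arrays are in that series, so it cannot account for the day 7 division. The arrays therefore hold a structure besides strain and stage.

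Mesothelial markers were lower in Dahl S at days 7 and 10. Of 16 markers written down, 15 were measured and 8 were called at 1 or more of these stages, all lower at both (medians -1.69 and -1.67) and also lower, though not called, in virgin uterus (-0.75) but not in placenta (0.03), while the 7 others had a median of -0.15 at day 7 and -0.21 at day 10. A median within-group correlation of 0.484 between the called markers could not tell whether 1 cell population varied in amount, although only 0.01% of 10000 random gene sets correlated as strongly. The median of the called markers was -1.63 at day 7 within the high-background arrays and -1.57 at day 10 within the low-background ones. The markers had been called with these same arrays. A kept difference was therefore likely in advance, and it does not argue against the background set. At day 10 each strain held 3 low-background arrays and 1 high-background array, so the sets were balanced there. A smaller share of the whole outer wall was argued against by a smooth muscle median of 0.51, which went the other way. Fat tissue markers were lower at the same stages (list medians -0.57 and -0.41), and a difference in how much attached tissue came with each piece may remain, as may a strain difference in the mesothelium.

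The day 7 strain calls could rest on animal 60, which resembled virgin uterus. The first form of this test, the count of calls kept without that animal, gave 54 of 123 and decided nothing by the threshold then set. It was replaced by the percent of the strain difference kept over those calls, which was 96.4. The calls had been made with animal 60 included, and a difference from a single array widens the spread and is seldom called. A high percent was therefore likely in advance, and it does not argue against that animal. Placed between Dahl S virgin uterus at 0 and Dahl S day 7 sites at 1, the other 4 Sprague Dawley sites lay at 0.814 or higher and animal 60 at 0.199. Because that scale was built from Dahl S arrays, it could not tell whether Sprague Dawley sites were at an earlier point of the same course.

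In placenta the labyrinth and cell cycle lists were lower and the decidual list higher in Dahl S. Adjusted over their list alone, 5 junctional zone and giant cell markers were higher and 5 lower. The rises went against less trophoblast of every kind as the source of these shifts. Background went with strain for these markers too, so they could not exclude it. A division of the arrays that goes with background may be the source, because pool 46, the Sprague Dawley pool with the background of the Dahl S pools (2.11 against 2.18 or more in the other 4), lay no further than 0.202 of the way from Dahl S to those 4 for any of the 3 lists, and with the division as a block the medians were -0.03, 0.01 and -0.07. A Dahl S sample labelled as pool 46 would place it likewise, but it was nearer Sprague Dawley at 4 of 5 strain markers and, in a second form counted after that one had decided nothing, outside the Dahl S range on the Sprague Dawley side at 4. As only 1 pool parts background from strain, arrays handled apart, pools with more decidua and less labyrinth, and a strain difference that pool 46 lacks cannot be told apart.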

How the results depend on the processing

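No call changed sign under any alternative that left out a single animal. That was nearly fixed in advance, because the calls were made with the same arrays. The order below is virgin, day 7, day 10 and placenta between strains, the Sprague Dawley and Dahl S steps to day 7, the same to day 10, and the strain differences in the 2 steps. With all 37 arrays in 1 fit the counts were 65, 679, 198, 122, 2421, 2404, 4539, 1641, 24 and 46. With array weights they were 104, 33, 1861, 882, 1562, 2033, 5871 and 1956, and 19 for the last. With only the groups compared they were 3, 5 and 26 for the uterine strain comparisons, 2 for the Sprague Dawley step to day 7, 378 and 1657 for the steps to day 10, and 0 for the strain difference in the step to day 10. One probe set per gene gave 11 in virgin uterus, 43 at day 10 and 1452 in the Sprague Dawley step to day 10. Leaving out the trend gave 198 in placenta, keeping only probe sets above the median level gave 9 for the last comparison, and quantile normalization gave 1 for the strain difference in the step to day 7. The other counts under these settings, and all under a robust trend, stayed within 1.5 times. The cause was not tested.

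Choices added after seeing the data changed more. The background block gave 10 in virgin uterus and 352, 512, 615 and 231 in the 4 gestation steps. Within low-background arrays 13 passed in virgin uterus, 247 at day 10, and 703 and 98 in the Dahl S steps. Within high-background arrays 1 passed at day 7, 210 at day 10, 0 and 581 in the Sprague Dawley steps, 4 in the Dahl S step to day 10 and 131 for the strain difference in that step; a lone array was assumed to vary like the others. Without Sprague Dawley animals 60 and 43 the counts were 13 in virgin uterus, 215 at day 10, 2335 and 1952 in the steps to day 7, 1109 in the Dahl S step to day 10, and 3 and 10 for the strain differences. The number series as a block gave 13 in virgin uterus, 188 at day 7, 489 and 734 in the steps to day 7 and 868 and 201 in those to day 10. Over the 16 assignments of the doubled numbers these ran from 3 to 15, 105 to 188, 282 to 529, 665 to 1201, 591 to 1127 and 164 to 366. Within the shorter series 2 passed in virgin uterus and 210 at day 10. Within the longer series 1 passed in virgin uterus, 6 at day 7, 317 at day 10, 40 and 124 in the steps to day 7, 957 and 18 in those to day 10, and 1 and 231 for the strain differences. In placenta the background block, which rests on 1 Sprague Dawley pool, gave 6 calls and 4 lists, and the background level as a covariate 8 calls and 12 lists. With that block the camera direction of the angiogenic (camera adjusted p = 0.215), matrix (0.483) and erythroid lists (0.607) reversed. The medians of the cell cycle, decidual, oestrogen and progesterone, and complement lists changed sign as well. Day 7 and day 10 arrays share 6 running numbers, but no label makes these pairs, 2 of 6 pairs had deviations correlated over 0.1, and 2 correlated best with their own number. A replicate block of these numbers gave 1730 and 553 calls in the steps to day 10 and 0 for the strain difference. For the other comparisons no paired analysis was possible because their groups share fewer than 2 numbers.

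Leaving out 1 animal at a time, the lowest and highest counts were 1 and 22 in virgin uterus, 22 and 163 at day 7, 29 and 145 at day 10, 67 and 2698 in placenta, 282 and 1766 and then 689 and 1004 in the steps to day 7, 921 and 3639 and then 221 and 596 in those to day 10, and 0 and 7 and then 0 and 9 for the strain differences. Of 250 named gene results, 183 were called, of which 94 held in every such fit and 89 were lost in some; 16 others were gained. With only the groups compared, 54 of 146 called gene results held. With an estimated correlation camera called 0 lists in all 10 comparisons, against 71 at the preset one. Without animal 43 it called 5 lists at day 10. Quantile normalization kept 68 of the 71.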

Other observations

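The contrast and gene families in this part were chosen only after the results had been seen.

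Averaged over the 3 uterine stages, genes of muscle and of mesothelium were among those with the largest differences between the strains, with no list tested on this average. Lmod1 (0.78 ± 0.18, SE), Mylk (0.74 ± 0.16), the small heat shock protein genes Hspb6 (0.94 ± 0.16) and Hspb7 (0.69 ± 0.15), Pgm5 (0.91 ± 0.16) and Popdc2 (0.63 ± 0.11) of muscle membranes, the matricellular gene Sparcl1 (0.98 ± 0.15) and the Wnt receptor partner Lgr5 (0.93 ± 0.20) were higher. Lrrn4 (-1.92 ± 0.26), Upk3b (-1.66 ± 0.25), Gpm6a (-1.68 ± 0.23), Adipoq (-1.81 ± 0.44), Hba-a1 (-1.44 ± 0.20), the neutrophil gene Retnlg (-1.40 ± 0.29) and the chemokine receptor Ccr1 (-1.06 ± 0.25) were lower. In all, 463 probe sets passed, 243 higher and 220 lower, 411 did with the background block, 325 of them in both, and 713 did with the number series as a block; the background block ended the calls of Lmod1 (adjusted p = 0.0502) and Adipoq (0.0542). Leaving out 1 animal gave between 267 and 632. Of 100 divisions within stages, only 1, the real one, gave as many, and the highest other gave 122. In placenta 31 of the 463 were called in the same direction and 1 in the opposite, where 2.48 were expected.

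Some members of 3 gene families with placental members differed in Dahl S placenta, with no family tested as a whole. The families were taken by the start of the gene symbol, so the cathepsins were not limited to placental ones. Of 21 prolactin family genes, 2 were higher and 2 lower over all genes, and 7 and 4 adjusted over the family alone, among them Prl3d4 at 1.12 ± 0.25 and Prl8a5 at -0.76 ± 0.17. Of 22 cathepsins none was higher and 1 lower over all genes, Ctsm (-1.26 ± 0.22). Adjusted over the family alone 9 were higher, such as Ctsk (1.21 ± 0.29) and Ctsc (1.04 ± 0.35), and 5 lower, which were Ctsm, Ctsq (-0.90 ± 0.19), Ctsr (-0.84 ± 0.22), Ctsrl1 (-0.41 ± 0.14) and Cts7l1 (-0.35 ± 0.11). Of 12 pregnancy-specific glycoprotein and Ceacam genes 3 were lower over all genes, Psg29 (-1.73 ± 0.22), Psg19 (-0.77 ± 0.10) and Ceacam1 (-0.69 ± 0.05), and none was higher; adjusted over the family alone 4 were lower, with Psgb1 (-1.25 ± 0.30), and none higher. In the fit with the background block, which rests on 1 Sprague Dawley pool, Psg29 was at -1.26 ± 0.34, Psg19 at -0.99 ± 0.16, Ceacam1 at -0.59 ± 0.09, Psgb1 at -0.45 ± 0.45 and Ctsm at -0.75 ± 0.36, none passing. Some members of these families are alike in sequence, and probes shared between them were not examined.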
